A study of Homo sapiens with 6 samples.

How the data were processed

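PolyA RNA of 6 cultures was sequenced, 1 library each: the lymphoma lines DAUDI and DOHH2 as parental, idelalisib-resistant and ibrutinib-resistant cells. Per the labels' protocols the libraries were made with a directional RNA kit, so the strand is kept. Per the submitters' processing notes, reads were handled with bcl2fastq and cutadapt, aligned to hg19 with TopHat2 and quantified with Cufflinks; the versions are not given in the sources used here. The deposited table of each library lists FPKM per isoform, that is fragments scaled by the authors to transcript length and to the number of mapped fragments, for 43490 RefSeq isoforms. The deposited tables also hold, per the file headers, a coverage signal that is not scaled to library size, the isoform length in nucleotides and lower and upper bounds of the FPKM. Read counts were not used here.

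FPKM were summed over the isoforms of a gene symbol per library (23844 genes), and log2(FPKM + 1) was taken. Genes with 1 FPKM or more in at least 1 of the 6 libraries were kept, which left 12337 genes, of which 12186 have an isoform of 300 nt or more. Left out were 528 isoforms with no gene name and 10 genes with an estimate marked as failed in any library. The deposited FPKM bounds were not used, since between 1670 and 2343 values per library lie outside their own bounds. Without counts, absolute depth is unknown. Relative depth was read from coverage per FPKM: against the DAUDI library labelled parental it was 1.04 and 1.42 in the idelalisib-resistant and ibrutinib-resistant DAUDI libraries and 0.979, 0.976 and 0.936 in the labelled parental, idelalisib-resistant and ibrutinib-resistant DOHH2 libraries. Genes at 1 FPKM or more numbered 10283 to 10693 per library. A value listed at 0 has no bound without counts, so no ratio is given for a gene listed at 0 in every library of a group, which is 1 library within a line and 2 libraries, 1 of each line, in limma.

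Samples were grouped by the cell line and state of their labels. With 1 library per group, each comparison within a line gives the difference of log2(FPKM + 1) per gene and the genes that differ by at least 1, with no test. For both lines together limma 3.58.1 was run on log2(FPKM + 1) with the cell line as a block, that is libraries paired by line, and the state as factor (6 libraries, 2 residual degrees of freedom, 2 prior degrees of freedom, empirical Bayes with trend, tests two-sided). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The median standard error was 0.24 for contrasts of states and 0.196 for the contrast of lines. The fit takes the lines as replicates of a state and assumes that all states vary alike. The lines were compared by r across genes, and both drugs within a line by overlap and covariance beside 20 simulations of unchanged libraries that share 1 control.

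The gene lists, 29 with 600 names, of which 597 are in the tables and 486 were tested, were B cell receptor signalling, the PI3K AKT mTOR pathway, FOXO, NF-kB, Wnt, MYC and p53 target genes, MAPK output, the BCL2 family, drug transport and metabolism, receptor tyrosine kinases, SRC and TEC family kinases, germinal centre, plasma cell and memory B cell genes, proliferation, interferon response, MHC class I and class II, homing and adhesion, cytokines and their receptors, hypoxia and glycolysis, cholesterol synthesis, amino acid and unfolded protein stress, heat shock and redox, and markers of T and NK, myeloid, stromal and epithelial, and erythroid cells. Within a line each list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. For both lines camera from limma was run with a preset correlation of 0.01 and, as an alternative, with an estimated one. Isoform shares were taken for genes with 10 FPKM or more in both libraries, and a share difference of 50 percentage points was counted.

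Samples, comparisons, tests, lists, the rule for named genes and the other settings to try were chosen before the data were examined. By this rule the text may name BTK and PIK3CD; in each comparison within a line, the 12 highest and 12 lowest genes at 5 FPKM or more in 1 of the libraries, without features under 300 nt, small RNAs, immunoglobulin and T cell receptor segments and unnamed loci; for each drug, the 12 genes in each direction with the largest smaller difference in both lines; up to 4 members of a list with the largest absolute difference; the 12 genes of smallest p for the resistance contrasts and 6 for the others; and the 6 isoforms with the largest share difference, in each case taken from the top, with some genes left out of the text. Names outside the rule are marked as chosen after their values were seen. The resistant libraries of a line were set against each other, and the libraries labelled parental against each other, after seeing the data, and the same rule was used.

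Settings tried by that choice were a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, scaling by the median of ratios or the upper quartile, the most abundant isoform in place of the sum, limma without trend, without the block, with only the 4 libraries compared, or without each library in turn, camera with an estimated correlation, and isoform shares at 30 FPKM or at 70 points. Added after seeing the data were keeping genes with failed estimates, the labelled parental library of the other line, features of 300 nt or more, and the lines compared in resistant libraries only.

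The fit was tested on simulated data with 12337 genes, 50 of them shifted at each size. With the residual spread of the real fit, 2, 27, 43 and 50 of 50 genes were found at a log2 change of 1, 2, 3 and 5, with 10 false calls. With the spread between the resistant DOHH2 libraries, 43, 47, 49 and 50 were found, with 18 false calls. Of 20 simulated lists of 25 members, 1 lay outside the central range of random lists with no shift, 19 with a shift of 0.5 and 20 with a shift of 1. Scripts used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3.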

Results

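RNA was sequenced from 6 cultures, with 1 library per group and no replicate library: DAUDI, a Burkitt lymphoma line, and DOHH2, a follicular lymphoma line with a BCL2 translocation, each as a parental, an idelalisib-resistant and an ibrutinib-resistant culture. Idelalisib inhibits the delta isoform of PI3K (PIK3CD) and ibrutinib inhibits the kinase BTK, both of which act below the B cell receptor. The question addressed is which transcripts differ between resistant and parental cells, and how far the lines and the drugs share these differences. Values are FPKM summed over the isoforms of a gene, for 12337 genes. Differences are on the scale log2(FPKM + 1), which understates ratios of weakly expressed genes, and a gene is called higher or lower when it differs by at least 1 on that scale. For a single line there is no replicate check, so no p-value is given.

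The libraries labelled parental did not group with the resistant libraries of the line they are labelled with. Across 12186 genes of 300 nt or more, the DAUDI and DOHH2 libraries labelled parental had a Pearson r of 0.991 with each other, and 60 genes differed between them. Each was far from the resistant libraries of its own line, with r of 0.736 and 0.722 in DAUDI and 0.730 and 0.737 in DOHH2 (3703 to 4213 genes differing). The resistant libraries followed their line: r was 0.980 within DAUDI (342 genes) and 0.992 within DOHH2 (77 genes), against 0.838 to 0.856 between the lines (2238 to 2642 genes). These correlations are across genes, and genes are not independent replicates. Every difference drawn below against a library labelled parental therefore holds for the library so labelled, and cannot be read as a change within one line.

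**Figure D1:**
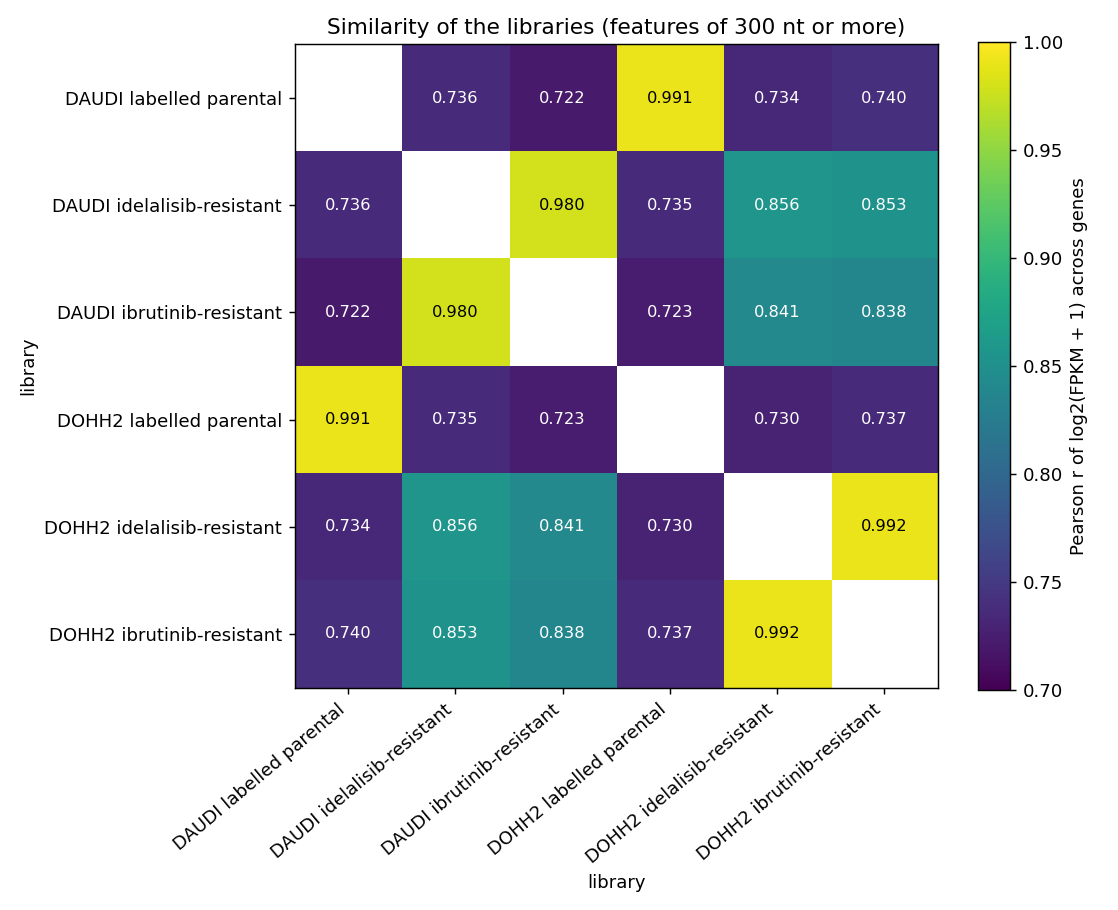
Pearson r across 12186 genes of 300 nt or more between each pair of the 6 libraries, on log2(FPKM + 1). The libraries labelled parental reach 0.991 with each other and 0.722 to 0.737 with the resistant libraries of their own line.

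Some genes with large differences between the lines or from a library labelled parental, CDKN2A, MTAP, BCL2, GSTM1 and UGT2B17, were chosen after their values were seen. In the order labelled parental, idelalisib-resistant, ibrutinib-resistant, the anti-apoptotic gene BCL2 stood at 59.7, 0.228 and 0.395 FPKM in DAUDI and at 51.6, 53.5 and 58.2 FPKM in DOHH2. The cell cycle inhibitor gene CDKN2A was listed at 0, 14.2 and 16.8 FPKM in DAUDI and at 0 in all DOHH2 libraries, and its neighbour MTAP at 0.0059, 6.36 and 6.19 FPKM in DAUDI and at 0 in DOHH2. BCL2, CDKN2A and MTAP thus set the library labelled parental apart in DAUDI and not in DOHH2. GSTM1 and UGT2B17, genes that are often deleted in the germ line, stood at 13.0 and 7.13 FPKM in the DOHH2 library labelled parental and were listed at 0 in both resistant DOHH2 libraries. In DAUDI, GSTM1 stood at 15.2, 4.18 and 1.29 FPKM and UGT2B17 at 3.64, 0.202 and 0.165 FPKM. None of these genes had an estimate marked as failed, since such genes were left out. The isoform tool may still list 0 for a gene that is expressed. CDKN2A is not alone in its stretch, by neighbours also chosen after their values were seen. CDKN2B-AS1 and FLJ35282 were listed at 0 in both libraries labelled parental and both resistant DOHH2 libraries. In the resistant DAUDI libraries they stood at 0.718 and 0.854 FPKM, and at 1.97 and 2.13 FPKM. Of the genes for the drug targets, PIK3CD was lower than in the libraries labelled parental, at 36.7, 13.2 and 15.3 FPKM in DAUDI and at 34.3, 13.6 and 12.2 FPKM in DOHH2. BTK differed by less than 1 on the log2 scale, at 68.4, 112 and 115 FPKM in DAUDI and at 72.1, 101 and 109 FPKM in DOHH2.

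**Figure D2:**
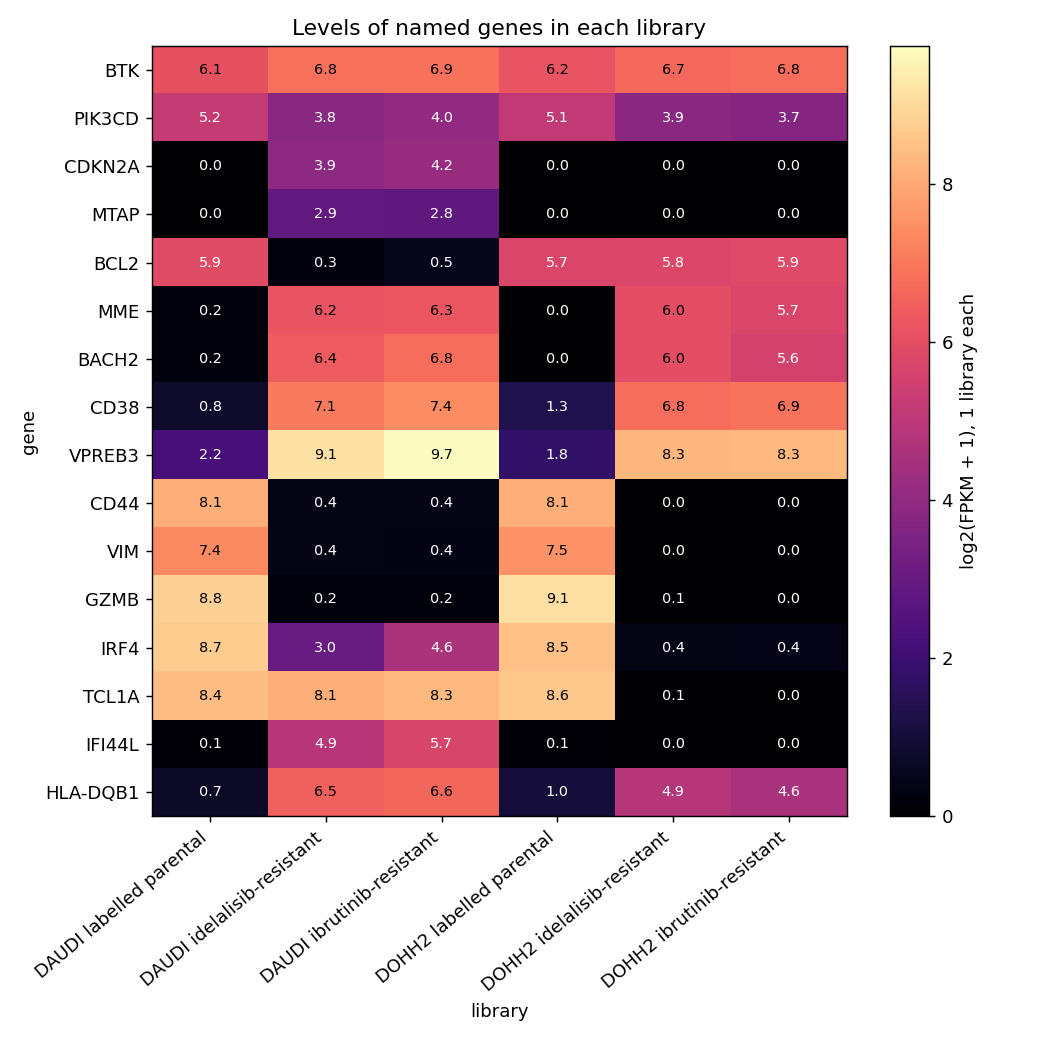
Level of 16 named genes in the 6 libraries as log2(FPKM + 1), in colour. BCL2 is high in both libraries labelled parental and in DOHH2 but not in the resistant DAUDI libraries (0.228 and 0.395 FPKM), and GZMB and CD44 are high only in the libraries labelled parental (451 and 277 FPKM in DAUDI).

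Against the DAUDI library labelled parental, both resistant DAUDI libraries held more mRNA of VPREB3, CD38, IGJ and BACH2 and less of GZMB and CD44. In the idelalisib-resistant library the largest differences upward were the surrogate light chain gene VPREB3 (6.93), TEX19 (6.53), the ectoenzyme gene CD38 (6.29), the immunoglobulin J chain gene IGJ (6.20), the transcription factor gene BACH2 (6.13), MME, which encodes CD10 (6.04), BMP7 (6.003) and PPDPF (5.99). The ibrutinib-resistant library held most of the same genes, led by the protease inhibitor gene SLPI (7.55), VPREB3 (7.53), CD38 (6.62), BACH2 (6.54), IGJ (6.43) and TEX19 (6.31). Lower than in the library labelled parental were the granzyme gene GZMB (-8.61 and -8.67 with idelalisib and ibrutinib resistance), the adhesion receptor gene CD44 (-7.71 and -7.70), LGALS1 (-7.50 and -7.18), the intermediate filament gene VIM (-6.97 and -6.99) and MNDA (-6.83 and -6.91). GZMB stood at 451 FPKM in the library labelled parental and at 0.15 and 0.11 FPKM in the resistant ones. In all, 1890 genes were higher and 1946 lower in the idelalisib-resistant library, and 2497 higher and 1804 lower in the ibrutinib-resistant one. The latter split, 58.1% higher, depends on the scaling. With libraries rescaled by the median of ratios 1899 were higher and 2214 lower (46.2% higher), and with idelalisib resistance 1722 and 2147. The median over all genes of the ibrutinib comparison then moved from 0.18 to -0.04. With upper quartile scaling 2168 were higher and 1967 lower with ibrutinib resistance (52.4% higher), and 1979 and 1899 with idelalisib resistance.

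Fixed gene lists are given by the number of measured members higher, lower and neither, the median difference, and its percentile among 10000 random lists matched on expression, which describes the list and tests nothing. Of the 17 germinal centre genes, 9 were higher, 2 lower and 6 neither in the idelalisib-resistant DAUDI library (median 1.06, percentile 99.99) and 10, 3 and 4 in the ibrutinib-resistant one (median 1.27, percentile 100). CD38, BACH2, MME and GCSAM (5.56 and 5.89) were furthest up. Plasma cell genes went both ways: 6 higher, 5 lower and 3 neither with idelalisib resistance (median -0.10, percentile 17.4), and 7, 5 and 2 with ibrutinib resistance (median 1.24, percentile 99.9). Among them CD38 and IGJ were higher. The transcription factor genes IRF4 (-5.73 and -4.13) and PRDM1 (-5.38 and -4.95), which drive plasma cell differentiation, and ITM2C (-5.27 and -5.33) were lower. Memory and activated B cell genes were mostly lower, 3 higher, 9 lower and 4 neither in both libraries (medians -1.76 and -1.35, percentile 0 in both). CD44, FCRL5 (-6.11 and -5.75) and TNFRSF13B (-5.53 and -5.17) differed most, with CD27 the other way (5.86 and 5.83).

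Signalling lists of DAUDI also stood below the library labelled parental in part. Members of B cell receptor signalling were 3 higher, 12 lower and 12 neither with idelalisib resistance (median -0.89, percentile 0) and 4, 10 and 13 with ibrutinib resistance (median -0.57, percentile 0): the phosphatase gene PTPN6 (-5.36 and -4.67), the exchange factor gene VAV2 (-4.69 and -4.89) and the kinase gene LYN (-3.31 and -2.89) were lower and BLK higher (3.51 in both). NF-kB target genes gave 2 higher, 12 lower and 10 neither in both libraries (medians -1.13 and -1.14, percentile 0 in both). BCL2A1 (-6.22 and -5.47), CCR7 (-6.19 and -5.01), IRF4, CCL22 (-5.45 and -5.47) and, upward, the cytokine gene LTB (4.38 and 4.25) stood furthest from 0. MAPK output genes gave 2, 7 and 3 in both (medians -1.79 and -1.66, percentile 0.01 in both), led by DUSP5 (-4.94 and -3.89) and EGR1 (-3.91 and -3.94). In contrast, FOXO target genes were mostly higher, 12, 5 and 4 with idelalisib resistance (median 1.57, percentile 100) and 14, 6 and 1 with ibrutinib resistance (median 2.18, percentile 100), although the members furthest from 0 lay below it: BNIP3 (45.5 FPKM in the library labelled parental against 0 and 0.0598 FPKM) and S1PR1 (-4.26 and -4.19). The PI3K AKT mTOR pathway was balanced, 6, 6 and 14 (median -0.07, percentile 26.1) and 8, 5 and 13 (median 0.10, percentile 31.2). The mTOR inhibitor gene DEPTOR was higher (5.14 and 5.66). Receptor tyrosine kinases were 9 higher, 2 lower and 3 neither (median 1.14, percentile 99.9) and 7, 2 and 5 (median 1.29, percentile 99.9). EGFR (3.42 and 4.09) and INSR (2.94 and 3.89) were higher and EPHA4 (-4.91 and -4.90) lower. SRC and TEC family kinases were mixed, 4, 4 and 3 (median 0.38, percentile 84) and 5, 3 and 3 (median 0.74, percentile 94.3). FGR was higher (4.86 and 4.36). Wnt target and receptor genes gave 3, 7 and 4 (median -0.78, percentile 2) and 2, 6 and 6 (median -0.47, percentile 4.77). NKD2 stood at 24.5 FPKM in the library labelled parental and was listed at 0 in both resistant ones, and WNT10A was lower (-3.64 in both).

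Most genes called in the interferon and antigen presentation lists were higher in resistant DAUDI cells than in the library labelled parental. Of 27 interferon response genes, 14 were higher, 3 lower and 10 neither with idelalisib resistance (median 1.54, percentile 100) and 17, 3 and 7 with ibrutinib resistance (median 2.19, percentile 100), led by IFI44L (4.75 and 5.56), IFI44 (4.72 and 5.22), IFIT3 (3.69 and 4.24) and RSAD2 (3.32 and 4.22). MHC class I genes were 6 higher, 1 lower and 7 neither (median 0.97, percentile 99.97) and 10, 1 and 3 (median 1.36, percentile 100). The immunoproteasome gene PSMB9 (2.56 and 2.93) and HLA-F (1.58 and 2.24) were higher and B2M, the light chain of class I, lower (2012 FPKM against 350 and 458 FPKM). MHC class II genes were 10 higher, 0 lower and 4 neither in both (medians 1.56 and 1.48, percentile 100 in both). HLA-DQB1 (5.77 and 5.94), HLA-DOB (4.28 and 4.13), HLA-DOA (2.96 and 3.10) and HLA-DQA1 (2.55 and 2.45) differed most.

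Lists of migration and metabolism in DAUDI mostly lay below the library labelled parental, and stress lists went apart. Hypoxia and glycolysis genes were 0 higher, 17 lower and 12 neither with idelalisib resistance (median -1.16, percentile 0) and 0, 14 and 15 with ibrutinib resistance (median -0.93, percentile 0). The mitophagy gene BNIP3 and the phosphofructokinase gene PFKP (-5.46 and -4.28) stood furthest from 0. Homing and adhesion genes gave 6, 10 and 5 (median -0.65, percentile 0.38) and 5, 10 and 6 (median -0.26, percentile 3.24). CD44, CCR7, GPR183 (-4.87 and -5.11) and ICAM3 (-4.92 and -4.87) lay furthest from 0. Cytokines and cytokine receptors gave 3, 13 and 12 (median -0.97, percentile 0.01) and 4, 13 and 11 (median -0.72, percentile 0.05). CCL22, IL2RB (-4.94 and -4.60), LTB and IL10 (-4.25 and -4.27) differed most. Genes of amino acid and unfolded protein stress were mostly higher, 13, 5 and 6 (median 1.06, percentile 100) and 16, 4 and 4 (median 1.82, percentile 100). With idelalisib resistance ATF3 (-4.80), PHGDH (-3.31) and SESN2 (3.31) lay furthest from 0, and with ibrutinib resistance SESN2 (3.98) and the glutathione degrading enzyme gene CHAC1 (3.58). Heat shock and redox genes gave 2, 7 and 11 (median -0.73, percentile 0.04) and 3, 6 and 11 (median -0.61, percentile 0.05). HMOX1 (-5.47 and -5.44) and HSPA1B (-3.27 and -2.65) stood furthest from 0. The p53 target genes gave 6, 2 and 13 (median 0.34, percentile 91) and 11, 1 and 9 (median 1.01, percentile 99.9). SESN2 and SESN1 (2.99) were highest with idelalisib resistance and SESN2 and TP53INP1 (3.49) with ibrutinib resistance. Cholesterol synthesis genes gave 1, 1 and 22 (median -0.38, percentile 0.34) and 3, 0 and 21 (median 0.08, percentile 16.8). Proliferation genes mostly differed little, 1, 4 and 24 (median -0.20, percentile 5.78) and 3, 5 and 21 (median -0.01, percentile 9.65), as did MYC target genes, 2, 1 and 24 (median 0.16, percentile 55.6) and 2, 3 and 22 (median -0.25, percentile 0.13), where the transferrin receptor gene TFRC was lower (-3.44 and -3.84).

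The BCL2 family of DAUDI gave 2 higher, 5 lower and 8 neither with idelalisib resistance (median -0.35, percentile 4.39) and 4, 5 and 6 with ibrutinib resistance (median 0.09, percentile 30.9). BCL2A1, BCL2 (-5.63 and -5.44) and the pro-apoptotic gene BCL2L11 (-3.61 and -3.97) were lower than in the library labelled parental and BIK higher (3.10 and 2.75). Drug transport and metabolism genes gave 5, 7 and 4 (median -0.77, percentile 0.78) and 6, 6 and 4 (median -0.71, percentile 0.87). The glutathione transferase genes MGST1 (-6.25 and -6.22) and GSTP1 (-5.51 and -5.22) were lower and the transporter genes ABCB4 (3.58 and 3.99) and ABCG1 (3.40 and 4.18) higher. Among genes at 5 FPKM or more this median was 0.84 and 0.77. Markers of other cell types were few at 1 FPKM or more. T and NK cell markers (6 measured of 18; 3, 2 and 3 at 1 FPKM or more in the labelled parental, idelalisib-resistant and ibrutinib-resistant library, 0 in another list) gave 1, 3 and 2 (median -0.40, percentile 27.2) and 2, 2 and 2 (median -0.08, percentile 40.4). GZMB and CD5 (-4.00 and -3.99) lay furthest from 0. Myeloid markers (8 of 17; 2, 6 and 6 at 1 FPKM or more, 1 in another list) gave 5, 2 and 1 in both (medians 1.26 and 1.53, percentiles 99.7 and 99.8). TYROBP (-3.97 and -3.84) and LYZ (3.88 and 3.69) differed most. Stromal and epithelial markers (4 of 17; 1, 2 and 2, with 3 in another list) gave 2, 1 and 1 in both (medians 0.63 and 0.69, percentiles 84 and 81.2). CDH1 (-4.69 and -4.48) and ACTA2 (2.23 and 3.82) stood furthest from 0. Erythroid markers (3 of 11; 0 at 1 FPKM or more in any DAUDI library, 0 in another list) gave 0, 0 and 3 (medians 0.05 and 0.04, percentiles 61.3 and 59.9). In all, 19 of the 29 lists lay outside the central 95% of random lists in each DAUDI comparison.

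Against the DOHH2 library labelled parental, the resistant DOHH2 libraries held more mRNA of PRKAR2B, TUBB3, BMP7 and VPREB3 and less of GZMB and TCL1A. In the idelalisib-resistant library the largest differences upward were the protein kinase A subunit gene PRKAR2B (7.62), the tubulin gene TUBB3 (7.46), BMP7 (6.78), NLRP4 (6.76), VPREB3 (6.49), CD52 (6.39) and IGJ (6.30), and the ubiquitin hydrolase gene UCHL1 stood at 69.7 FPKM against a listed 0. The ibrutinib-resistant library was led by PRKAR2B (7.45), TUBB3 (7.17), NLRP4 (6.69), BMP7 (6.57), VPREB3 (6.51) and CD52 (6.40). Lower were GZMB (554 FPKM in the library labelled parental, 0.042 FPKM and a listed 0 in the resistant ones), the oncogene TCL1A (390 FPKM against 0.05 and a listed 0) and its neighbour TCL1B (352 FPKM against a listed 0 and 0.06), CD44 (279 FPKM against a listed 0 and 0.02), IRF4 (-8.10 and -8.06), VIM (182 FPKM against 0.015 and a listed 0) and GATM (-7.44 and -7.60). In DAUDI, by comparison, TCL1A stood at 344, 282 and 320 FPKM. In all, 1980 genes were higher and 1941 lower with idelalisib resistance, and 1842 higher and 1933 lower with ibrutinib resistance. With libraries rescaled by the median of ratios 1630 were higher and 2163 lower with idelalisib resistance (43.0% higher), which turns the balance, and 1652 and 2110 with ibrutinib resistance, as the median over all genes of the idelalisib comparison moved from 0.08 to -0.04.

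B cell state lists of DOHH2 differed from the library labelled parental in the same directions as in DAUDI for germinal centre and memory genes. Germinal centre genes were 11 higher, 3 lower and 3 neither with both resistances (medians 2.33 and 2.30, percentile 100 in both). BACH2 (5.997 and 5.53), MME (5.98 and 5.67), GCSAM (5.74 and 5.87) and CD38 (5.48 and 5.62) lay furthest from 0. Memory and activated B cell genes were 1 higher, 10 lower and 5 neither in both (medians -1.61 and -1.39, percentile 0 in both). CD44, FCRL5 (-5.93 and -5.79) and TNFRSF13B (59.1 FPKM in the library labelled parental, listed at 0 in both resistant ones) differed most. Plasma cell genes gave 3, 6 and 5 in both (medians -0.39 and -0.33, percentiles 2.04 and 3.93). IRF4 and PRDM1 (-6.04 and -5.998) were lower and IGJ (6.30 and 5.997) higher.

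Among signalling lists of DOHH2, NF-kB target genes stood furthest below the library labelled parental: 0 higher, 19 lower and 5 neither in both libraries (medians -1.74 and -1.80, percentile 0 in both). IRF4, CCR7 (74.5 FPKM against a listed 0 in both), BCL2A1 (-5.13 and -5.21) and CCL22 (25.9 FPKM against a listed 0 in both) stood furthest from 0. B cell receptor signalling gave 2, 9 and 16 with idelalisib resistance (median -0.77, percentile 0) and 2, 10 and 15 with ibrutinib resistance (median -0.56, percentile 0.01). The protein kinase C gene PRKCB (-5.42 and -5.17), PTPN6 (-3.26 and -3.27) and LYN (-3.09 and -3.39) lay furthest from 0, with BLK higher (2.86 and 2.89). FOXO target genes gave 11, 6 and 4 in both (medians 1.36 and 1.22, percentile 100 in both). BCL6 was higher (3.60 and 3.46), and BNIP3 (48.9 FPKM against a listed 0 in both), S1PR1 (-4.07 and -4.05) and KLF2 (-3.64 and -3.74) were lower. The PI3K AKT mTOR pathway gave 6, 4 and 16 in both (medians 0.37 and 0.18, percentiles 90.4 and 70.1). DEPTOR (5.54 and 5.18) and PIK3CG (3.06 and 3.14) differed most. MAPK output genes gave 4, 4 and 4 with idelalisib resistance (median -0.33, percentile 9.38) and 1, 6 and 5 with ibrutinib resistance (median -1.17, percentile 0.08). DUSP5 was lower (-6.32 in both), and FOS was higher with idelalisib resistance (2.65, against 0.24 with ibrutinib resistance). Receptor tyrosine kinases were balanced, 4, 3 and 7 in both (percentiles 54.1 and 53.5). EPHA4 stood at 19.6 FPKM in the library labelled parental and was listed at 0 in both resistant ones, while INSR was listed at 0 there and stood at 10.3 and 9.09 FPKM in the resistant ones. SRC and TEC family kinases gave 4, 4 and 3 (median 0.40, percentile 86.1) and 5, 4 and 2 (median 0.59, percentile 96.1). LCK was higher (4.25 and 5.002). Wnt target and receptor genes gave 2, 4 and 8 in both (medians -0.38 and -0.40, percentiles 11.1 and 10.5). WNT10A (-4.01 and -2.92) and NKD2 (21.9 FPKM in the library labelled parental, then a listed 0 and 2.33 FPKM) stood furthest from 0.

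The medians of the interferon and MHC lists lay below the library labelled parental in DOHH2 and above it in DAUDI, although single MHC class II genes were higher in both lines. Interferon response genes were 1 higher, 17 lower and 9 neither with idelalisib resistance (median -1.47, percentile 0) and 0, 18 and 9 with ibrutinib resistance (median -1.50, percentile 0). IFITM1 (-3.93 and -4.18), MX2 (-3.90 and -3.05), OAS2 (-3.74 and -2.77) and MX1 (-3.71 and -3.62) lay furthest from 0 with idelalisib resistance. MHC class I genes gave 0, 7 and 7 (median -1.23, percentile 0) and 0, 6 and 8 (median -0.76, percentile 0.07). PSMB9 (-3.24 and -2.67) and HLA-F (-3.17 and -2.93) differed most. MHC class II genes gave 4, 5 and 5 in both (medians -0.70 and -0.66, percentiles 0.04 and 0.11). HLA-DQB1 (3.81 and 3.55) and HLA-DOB (3.45 and 3.61) were higher and HLA-DQA1 (-3.05 and -2.31) lower.

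Hypoxia and glycolysis genes of DOHH2 were 0 higher, 22 lower and 7 neither than in the library labelled parental with idelalisib resistance (median -1.66, percentile 0) and 0, 17 and 12 with ibrutinib resistance (median -1.06, percentile 0). BNIP3, the aldolase gene ALDOC (-4.31 and -1.82) and the lactate transporter gene SLC16A3 (15.2 FPKM in the library labelled parental, listed at 0 in both resistant ones) were lowest with idelalisib resistance. Cytokines and cytokine receptors gave 2, 21 and 5 (median -1.42, percentile 0) and 2, 22 and 4 (median -1.51, percentile 0). The shared cytokine receptor chain gene IL2RG (-5.63 and -5.54) and IL2RB (33.7 FPKM against a listed 0 in both) stood furthest from 0. Homing and adhesion genes gave 4, 9 and 8 in both (median -0.35 in both, percentiles 2.09 and 3.64). CD44, CCR7 and GPR183 (-5.80 and -5.70) lay furthest from 0. Heat shock and redox genes gave 3, 11 and 6 in both (medians -1.59 and -1.48, percentile 0 in both). HSPA1B (-6.21 and -6.37), HSPA1A (-6.10 and -6.16) and HSPB1 (-6.46 and -5.44) differed most with idelalisib resistance. Cholesterol synthesis genes gave 1, 6 and 17 (median -0.60, percentile 0) and 1, 8 and 15 (median -0.63, percentile 0.01). LSS was lower (-1.58 and -1.53). Amino acid and unfolded protein stress genes gave 8, 3 and 13 (median 0.31, percentile 83.7) and 6, 4 and 14 (median 0.24, percentile 83.5). ATF3 (36.1 FPKM against 0.0168 and a listed 0) and VLDLR (6.63 FPKM against 0.0085 and a listed 0) were lower and ASNS higher (2.60 and 1.98). The p53 target genes gave 7, 3 and 11 (median 0.00, percentile 30.8) and 7, 4 and 10 (median -0.08, percentile 22.4). SESN1 (2.75 and 2.82), SESN2 (2.52 and 1.85) and TP53INP1 (2.20 and 2.21) stood furthest from 0 with idelalisib resistance. Proliferation genes gave 4, 3 and 22 (median 0.05, percentile 30.5) and 7, 2 and 20 (median 0.43, percentile 97.7). CDT1 (1.74 and 1.86) and E2F1 (1.52 and 1.98) were higher and MCM5 lower (-2.27 and -1.85). MYC target genes gave 1, 2 and 24 in both (medians 0.10 and -0.02, percentiles 41.9 and 25.8), and TFRC was lower (-3.63 and -3.40).

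The BCL2 family of DOHH2 gave 2 higher, 6 lower and 7 neither with idelalisib resistance (median -0.91, percentile 0.01) and 1, 8 and 6 with ibrutinib resistance (median -1.15, percentile 0). BCL2A1, BCL2L11 (-2.77 and -2.63) and BIK (3.76 FPKM in the library labelled parental, listed at 0 in both resistant ones) were lower. Drug transport and metabolism genes gave 3, 6 and 7 in both (medians -0.51 and -0.34, percentiles 3.41 and 8.74). MGST1 (-6.08 with idelalisib resistance, and 78.2 FPKM against a listed 0 with ibrutinib resistance) and GSTM1 lay furthest from 0. T and NK cell markers (3, 1 and 1 at 1 FPKM or more in the labelled parental, idelalisib-resistant and ibrutinib-resistant library) gave 1, 3 and 2 in both (medians -1.54 and -1.53, percentiles 1.07 and 0.94). GZMB and CD5 (15.5 FPKM in the library labelled parental, listed at 0 in both resistant ones) differed most. Myeloid markers (3, 1 and 1) gave 0, 3 and 5 in both (medians -0.07 and -0.21, percentiles 53.8 and 40.2). TYROBP (-2.97 and -3.22) and CD68 (-2.79 and -2.27) stood furthest from 0. Stromal and epithelial markers (1, 2 and 2) gave 1, 1 and 2 in both (medians 0.42 and 0.43, percentiles 78.2 and 78.6). CDH1 (26.6 FPKM against a listed 0 and 0.0064) and DCN (1.72 and 2.71) lay furthest from 0. Erythroid markers (3, 0 and 0) gave 0, 3 and 0 in both (median -1.61 in both, percentiles 2.01 and 1.80). HBB stood at 3.39 FPKM in the library labelled parental and was listed at 0 in both resistant ones. In all, 17 of the 29 lists lay outside the central 95% of random lists in each DOHH2 comparison.

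**Figure D3:**
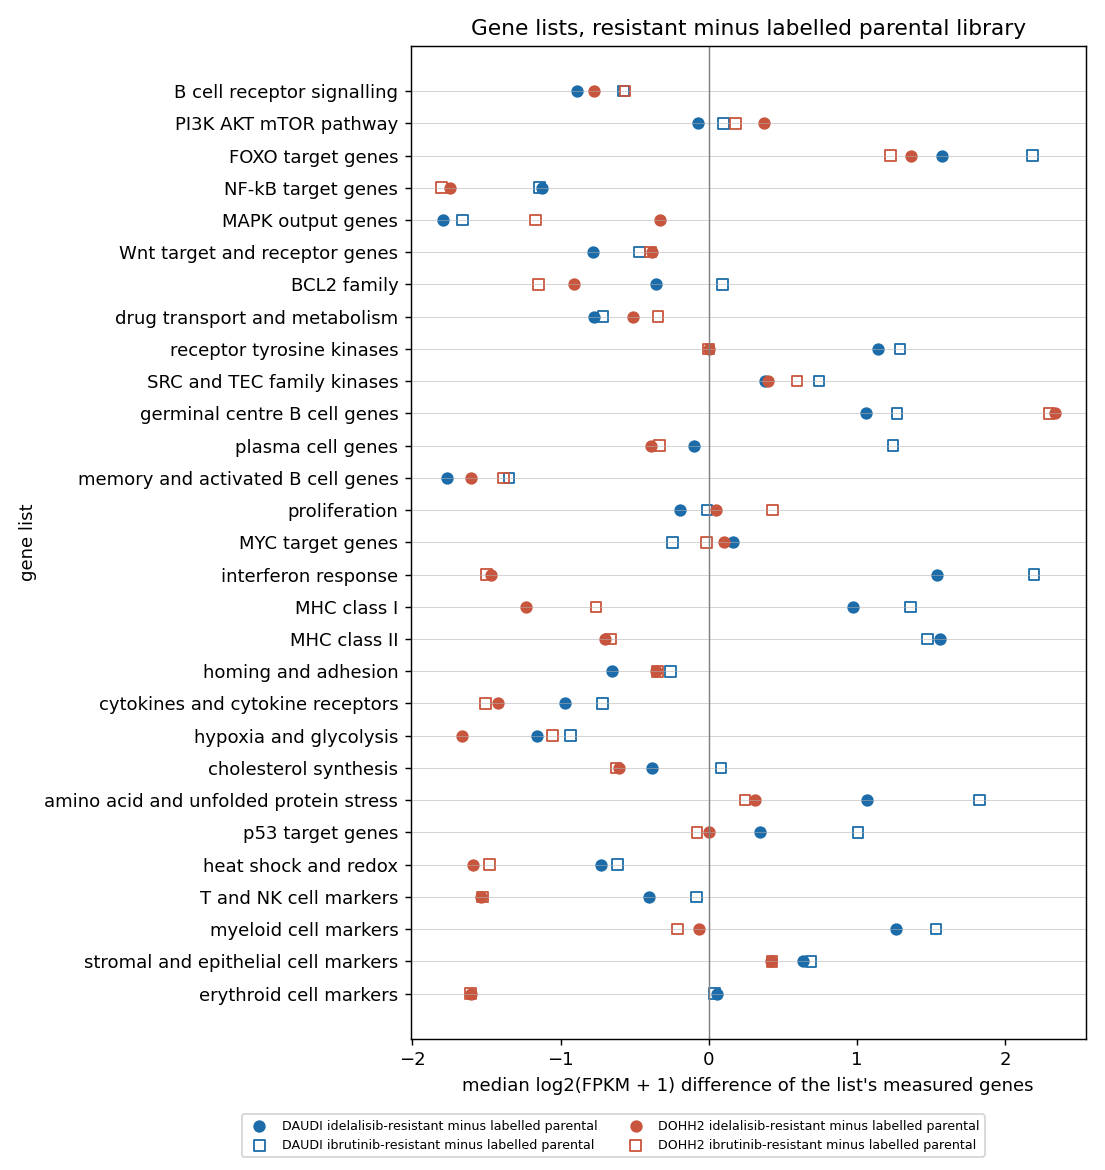
Median log2(FPKM + 1) difference of the measured genes of 29 fixed lists, resistant minus labelled parental, for DAUDI (blue) and DOHH2 (red), with idelalisib resistance as filled circles and ibrutinib resistance as open squares. The medians of the interferon response lie at 1.54 and 2.19 in DAUDI and at -1.47 and -1.50 in DOHH2.

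With the lines as replicates in limma, GZMB, CD44 and SLC12A7 fell and GCSAM rose in resistant cells against the libraries labelled parental. With idelalisib resistance the smallest p-values (adjusted p = 0.00428 each) were those of the small nucleolar RNA SNORD83B, listed at 0 in every library but the idelalisib-resistant ones (722 and 856 FPKM), GZMB (-8.84), CD44 (-7.92), the potassium chloride cotransporter gene SLC12A7 (-6.79), GCSAM (5.65), MNDA (-6.97), the cyclin gene CCND2 (-6.46), SCARB2 (-6.38), TUBB6 (-6.40), IGJ (6.25), GPR15 (-5.94) and MGST1 (-6.16). With ibrutinib resistance (adjusted p = 0.00425 each) the first were GZMB (-8.89), CD44 (-7.90), GCSAM (5.88), SLC12A7 (-6.69) and MNDA (-7.01). In all, 1134 genes rose and 1285 fell with idelalisib resistance, and 1233 rose and 1193 fell with ibrutinib resistance. With libraries rescaled by the median of ratios 1078 rose and 1596 fell with idelalisib and 1075 and 1548 with ibrutinib resistance, so the balance of the latter turns with the scaling. With only the 4 libraries of the states compared, 34 rose and 116 fell with idelalisib and 0 and 0 with ibrutinib resistance, and with no filter 389 and 1014, and 419 and 984. The libraries labelled parental are nearly alike, so the lines may not give independent controls. Without any 1 of the 4 resistant libraries no gene was called in either comparison. Calls remained without a library labelled parental. That fit rests on 1 control and takes its spread from the resistant libraries alone, so it does not test the controls. Among genes with the largest smaller difference in both lines were VPREB3, IGJ, BMP7, BACH2 and MME upward and GZMB, CD44, VIM, MNDA and SLC12A7 downward.

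Against the libraries labelled parental, genes of hypoxia and glycolysis, NF-kB, cytokines and memory cells were lower as lists in resistant libraries. Germinal centre genes were higher. These calls come from camera on the fit of both lines, with a preset correlation of 0.01. None of these calls holds with an estimated correlation. The lists are not independent, since names occur in more than 1 list. Also in another list were 11 NF-kB, 7 cytokine, 4 germinal centre, 3 memory and 3 hypoxia and glycolysis names. Here and in the next paragraph, fell and rose mean lower and higher than in the libraries labelled parental, not a change within a line. Hypoxia and glycolysis genes fell with idelalisib resistance (adjusted p = 2.04e-09; adjusted p = 0.563 with an estimated correlation; 0 members rose and 15 fell over all genes tested, 0 and 22 adjusted over the list alone) and with ibrutinib resistance (adjusted p = 3.62e-07; adjusted p = 0.549 with an estimated correlation; 0 and 12, and 0 and 14 adjusted over the list alone). For NF-kB target genes the values were 2.32e-06 (adjusted p = 0.563 with an estimated correlation; 0 and 12, and 0 and 14 adjusted over the list alone) and 1.58e-06 (adjusted p = 0.549 with an estimated correlation; 0 and 12, and 0 and 15 adjusted over the list alone). Germinal centre genes rose (adjusted p = 0.00086 with idelalisib and 0.0026 with ibrutinib resistance; adjusted p = 0.563 and 0.549 with an estimated correlation), with 9 members up and 0 down over all genes tested in both, and 10 and 0, and 10 and 1, adjusted over the list alone. Memory and activated B cell genes fell (adjusted p = 0.000362 and 0.000478; adjusted p = 0.85 and 0.806 with an estimated correlation), with 1 and 8, and 1 and 6, members up and down, against 1 and 10 in both adjusted over the list alone. Cytokines and cytokine receptors fell (adjusted p = 0.000298 and 0.000127; adjusted p = 0.563 and 0.549 with an estimated correlation), with 2 up and 10 down in both, and 2 and 14 adjusted over the list alone. Heat shock and redox genes passed with ibrutinib resistance only (adjusted p = 0.0392; adjusted p = 0.872 with an estimated correlation; 1 up and 4 down, and 2 and 9 adjusted over the list alone); with idelalisib resistance the adjusted p was 0.0592 (0 up and 6 down, and 1 and 9 adjusted over the list alone), and the difference between the drugs did not pass (adjusted p = 0.799).

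The remaining lists did not pass camera with the preset correlation (adjusted p 0.0592 to 0.893 with idelalisib and 0.0615 to 0.953 with ibrutinib resistance). By limma against the libraries labelled parental, PIK3CD was lower (-1.34, adjusted p = 0.0194, with idelalisib and -1.31, adjusted p = 0.0202, with ibrutinib resistance). BTK, the other drug target gene, did not pass in the same fit (0.59, adjusted p = 0.0665, and 0.67, adjusted p = 0.052). These p-values take the nearly alike libraries labelled parental as independent controls. In B cell receptor signalling, 1 member rose and 9 fell with idelalisib resistance (3 and 10 adjusted over the list alone) and 2 and 8 with ibrutinib resistance (3 and 8). PTPN6 (-4.31 and -3.97) and VAV2 (-3.54 and -3.67) fell furthest. FOXO target genes gave 9 and 4 (11 and 4 adjusted over the list alone) and 11 and 4 (11 and 5), and BNIP3 (0 to 0.0598 FPKM in resistant libraries) and S1PR1 (-4.16 and -4.12) fell furthest. The PI3K AKT mTOR pathway gave 5 and 4 with both drugs, over all genes tested and adjusted over the list alone, and DEPTOR rose most (5.34 and 5.42). In the same order, and with counts adjusted over the list alone in brackets, members up and down with idelalisib and then ibrutinib resistance were: MAPK output 2 and 3 (2 and 4), 1 and 4 (1 and 4); Wnt 0 and 2 (0 and 2) in both; BCL2 family 0 and 3 (1 and 4), 0 and 3 (2 and 4); drug transport 3 and 5 (3 and 6), 3 and 4 (3 and 6). Receptor tyrosine kinases gave 2 and 2 (3 and 2), then 3 and 2 (3 and 2), SRC and TEC family kinases 3 and 3 (4 and 4), then 4 and 3 (5 and 5), plasma cell genes 3 and 5 (3 and 5) with both drugs, and homing and adhesion 2 and 7 (2 and 7), then 2 and 7 (3 and 7). Proliferation gave 1 and 2 (0 and 1), then 2 and 1 (2 and 1), MYC target genes 1 and 1 (0 and 1) with both, interferon response 0 and 3 (0 and 3) with both, MHC class I 0 and 0 (0 and 0) with both, MHC class II 3 and 0 (3 and 0) with both, and cholesterol synthesis 0 and 1 (0 and 0) with both. Amino acid and unfolded protein stress gave 3 and 2 (3 and 2), then 3 and 3 (3 and 3), p53 target genes 4 and 2 (6 and 2), then 5 and 1 (8 and 2). Among markers of other cell types, T and NK cell and myeloid markers gave 0 and 2 (0 and 2) with both, stromal and epithelial markers 0 and 1 (0 and 1) with both, and erythroid markers 0 and 0 (0 and 0) with both.

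In some of the lists that did not pass, the median, the mean and the direction of the test differ in sign. With idelalisib resistance these were proliferation (median 0.03, mean -0.06), MYC target genes (0.15, -0.01), myeloid (0.58, -0.03) and stromal markers (0.74, -0.43), of which MYC target genes were tested upward and the others downward. With ibrutinib resistance plasma cell genes (median 0.70, mean -0.34), interferon response (-0.02, 0.19), MHC class I (0.13, 0.06), myeloid (0.69, -0.06) and stromal markers (1.001, -0.06) were tested downward. Between ibrutinib and idelalisib resistance 9 lists with small medians, from -0.02 for receptor tyrosine kinases to 0.13 for amino acid and unfolded protein stress, were tested downward: these and NF-kB, drug transport, germinal centre, MHC class II, cytokines, heat shock and myeloid markers. Between the lines B cell receptor signalling (median 0.09, mean -0.06), the PI3K AKT mTOR pathway (-0.04, 0.02) and SRC and TEC family kinases (-0.05, -0.03) were tested upward, and proliferation (-0.06, 0.01) and heat shock and redox genes (0.05, -0.12) downward. Every list that passed had the same sign in all 3.

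Differences of the lines against their libraries labelled parental were related across genes, and genes are not independent replicates. For idelalisib resistance Pearson r between DAUDI and DOHH2 was 0.630 and Spearman rho 0.640, and for ibrutinib resistance 0.589 and 0.593; across the drugs r was 0.615 (DAUDI idelalisib, DOHH2 ibrutinib) and 0.595. Higher in both lines were 1006 genes with idelalisib resistance (303 for independent lists) and 1065 with ibrutinib resistance (373), and lower in both 1241 (306) and 1152 (283). Opposite differences were shown by 148 and 180 genes; among the largest, chosen after their values were seen, the cytokine gene LTB was 4.38 in DAUDI and -2.90 in DOHH2 with idelalisib resistance, PSMB9 2.56 and -3.24, ISG15 2.64 and -3.04, MYBPC2 -1.07 and 4.87, and the serine synthesis gene PHGDH -3.31 and 2.09. The nearly identical libraries labelled parental act as one control for both lines, so part or all of this relation may come from that shared control. The counts for independent lists do not allow for it.

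Within a line, both drugs were compared with the same library labelled parental. VPREB3, CD38, BACH2, IGJ and MME were higher and GZMB, CD44 and VIM lower with both drugs in DAUDI, and 1688 genes were higher and 1631 lower with both, where independent lists would share 383 and 285 and simulated unchanged libraries with a shared control 87.8 and 90. In DOHH2, 1653 were higher and 1803 lower with both, against 296 and 304 for independent lists and 35.3 and 37.5 in the simulation. Across genes r was 0.901 in DAUDI and 0.943 in DOHH2, against 0.499 and 0.498 in the mean of 20 simulations. The covariance was 1.86 in DAUDI against a simulated 0.217 (difference 1.64) and 1.93 in DOHH2 against 0.118 (difference 1.81). In the simulation the control varies no more than the resistant libraries do, whereas the real one lies far from both. That distance enters both comparisons and could by itself give such an excess. The simulation therefore cannot show how much the drugs share.

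The resistant libraries of a line can be compared without any library labelled parental; this comparison of single libraries was added after seeing the data. In DAUDI, higher with ibrutinib than with idelalisib resistance were the surrogate light chain gene IGLL1 (3.32, from 2.89 to 37.8 FPKM), RPL21 (3.30), PARP14 (3.15) and the recombinase genes RAG2 (3.04, from 0.95 to 15.0 FPKM) and RAG1 (2.88, from 0.55 to 10.4 FPKM). Lower were NLGN1 and COBLL1 (7.04 and 6.82 FPKM against a listed 0), MYO1D (-2.68), JUN (-2.46, from 14.0 to 1.72 FPKM) and the histone genes HIST1H2AG (-2.29) and HIST1H2AM (-2.22). Among genes of 300 nt or more 246 were higher and 96 lower, and 153 and 111 with libraries rescaled by the median of ratios, as the median over all genes moved from 0.14 to 0.01. The ibrutinib-resistant DAUDI library also stood apart from the other 5 in depth (1.42 times the DAUDI library labelled parental). It stood apart too in the FPKM listed for the microRNA precursor MIR663A, chosen after its values were seen (9945 FPKM against 33645 to 48797 FPKM). Of the lists, 7 lay outside the central 95% of random lists: interferon response (5 higher, 0 lower, 22 neither, median 0.68, percentile 100; IFITM1 2.06, IFI6 1.89), plasma cell genes (4, 0 and 10, median 0.55, percentile 100; IRF4 1.60), amino acid and unfolded protein stress (5, 0 and 19, median 0.62, percentile 100; ATF3 1.41), cholesterol synthesis (0, 0 and 24, median 0.47, percentile 100; MSMO1 0.84), p53 target genes (4, 0 and 17, median 0.47, percentile 99.99; GDF15 1.51), MYC target genes (0, 2 and 25, median -0.40, percentile 0; NOP58 -1.16) and receptor tyrosine kinases (1, 1 and 12, median -0.04, percentile 1.25; FGFR1 1.77).

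In DOHH2 the resistant libraries lay closer, with 56 genes of 300 nt or more higher and 21 lower with ibrutinib than with idelalisib resistance. Higher were HSBP1L1 (3.12), the kinase gene MAPK13 (2.63), LGALS1 (2.55) and the aldolase gene ALDOC (2.49), and lower were COMMD7 (-2.55), the immediate early genes FOS (-2.41, from 7.94 to 0.69 FPKM) and EGR1 (-1.72, from 5.77 to 1.05 FPKM), and BDKRB2 (-2.03). Outside the central 95% of random lists lay 5 lists: MAPK output genes (0 higher, 4 lower, 8 neither, median -0.34, percentile 0; FOS and EGR1), hypoxia and glycolysis (3, 0 and 26, median 0.31, percentile 100; ALDOC), proliferation (1, 0 and 28, median 0.26, percentile 100; MCM4 1.11), amino acid and unfolded protein stress (0, 1 and 23, median -0.31, percentile 0; CHAC1 -1.36) and MHC class I (0, 0 and 14, median 0.19, percentile 100; PSMB8 0.72).

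With both lines in limma, 1 gene differed between ibrutinib and idelalisib resistance: SNORD83B, listed at 0 in both ibrutinib-resistant libraries and at 722 and 856 FPKM in the idelalisib-resistant ones (adjusted p = 0.01). This call was lost without any 1 of the 6 libraries, with no filter and with only the 4 resistant libraries. Other small nucleolar RNAs, chosen after their values were seen, differed widely in opposite directions in the lines. With idelalisib resistance against the libraries labelled parental, SNORA40 was higher in DAUDI and lower in DOHH2, and SNORD97 lower in DAUDI and higher in DOHH2. The downward differences were the same with both drugs, as a listed 0 in the resistant libraries would give. No size is therefore printed. Next came other small nucleolar RNAs that did not pass, SNORD16 (listed at 0 with idelalisib resistance, 304 and 541 FPKM with ibrutinib resistance, adjusted p = 0.0514) and SNORA37 (43.8 and 61.7 FPKM against a listed 0, adjusted p = 0.0702), then TRIM74 (1.46, adjusted p = 1). At unadjusted p under 0.05, 49 genes were higher and 22 lower, and among features of 300 nt or more limma called no gene. By camera with a preset correlation, MYC target genes (adjusted p = 3.8e-11, median -0.24) and MAPK output genes (adjusted p = 0.00575, median -0.33) fell and hypoxia and glycolysis (adjusted p = 1.12e-07, median 0.34), proliferation (adjusted p = 0.000295, median 0.21), plasma cell (adjusted p = 0.027, median 0.33) and cholesterol synthesis genes (adjusted p = 0.027, median 0.18) rose. None of the 6 holds with an estimated correlation (adjusted p = 0.947 with an estimated correlation in each), and 0 members of any list passed over all genes tested or adjusted over the list alone.

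Between the lines, limma called no gene over all 6 libraries (DOHH2 minus DAUDI, smallest adjusted p = 0.389), with 431 genes higher and 499 lower at unadjusted p under 0.05. Without the DAUDI library labelled parental 797 genes were higher and 942 lower in DOHH2, without the DOHH2 one 799 and 942, and without any 1 resistant library 0 and 0. Smallest in p, none past the threshold, were the microRNA genes MIR1244-2 (2.16) and MIR1244-3 (2.43), the cytokine gene IL32 (-1.37), DNAJC12 (0.99) and the lipoxygenase gene ALOX5 (1.33). Among the 4 resistant libraries alone, a comparison added after seeing the data, 868 genes were higher and 1046 lower in DOHH2. Between the libraries labelled parental the heat shock genes HSPA6 (3.49), HSPA1A (3.09) and HSPA1B (3.09) were higher in the one labelled DOHH2 and RGS18 (-1.65), EGR1 (-1.45) and EGR2 (-1.36) lower. Over all 6 libraries camera with a preset correlation put interferon response (adjusted p = 2.04e-05, median -1.77), MHC class I (adjusted p = 0.00367, median -1.33), NF-kB target (adjusted p = 0.00367, median -0.48), cholesterol synthesis (adjusted p = 0.00367, median -0.53) and MHC class II genes (adjusted p = 0.0296, median -1.10) lower in DOHH2, with 0 members called over all genes tested or adjusted over the list alone. None of the 5 holds with an estimated correlation (adjusted p = 0.864 with an estimated correlation in each).

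Isoform shares differed at the leukocyte phosphatase gene PTPRC (CD45) in the same way in all 4 comparisons with a library labelled parental. Its 5429-nt isoform took 20.04% of the gene's FPKM in the DAUDI and 28.8% in the DOHH2 library labelled parental, and 99.5% in each of the 4 resistant libraries. All 4 comparisons rest on the nearly alike libraries labelled parental. They are therefore not independent, and no share difference from those libraries can be read as a change within a line. In the idelalisib-resistant DAUDI library the largest differences were those of an isoform of HIST1H2BD (14.7 to 98.3%), PTPRC, OAS1 (24.4 to 99.2%) and CD53 (72.8% to a rounded 0), and with ibrutinib resistance those of PARP2 (2.79 to 100%), RAP1GDS1 (87.0 to 0.011%), MARCH1 (100 to 17.2%) and GAB2 (0.011 to 81.7%). In DOHH2 they were those of HLA-DRB1 (100% to a rounded 0), NDUFC1 (95.0 to 0.004%) and TOMM40 (7.82 to 99.6%) with idelalisib resistance. An isoform's share differed by at least 50 percentage points in 17 of 1957 genes at 10 FPKM or more in DAUDI with idelalisib resistance, 26 of 2058 with ibrutinib resistance, and 27 of 1959 and 24 of 1968 in DOHH2. Between the resistant libraries of a line it did so in 3 of 2426 genes in DAUDI and 2 of 2453 in DOHH2, and between the libraries labelled parental in 2 of 2377.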

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

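Of the tests below, those of a single culture, of the line differences, of a shared shift, of a batch as the whole cause, of a swap, of a shared control and of the batch of the ibrutinib-resistant DAUDI library were chosen only after the result was seen; those of RNA quality, of depth and of other splits were chosen before. The libraries labelled parental lie closer to each other than to any resistant library. Against the explanation that each is the culture from which the resistant cells of its line came stands that of 252 genes that set the resistant libraries of the lines apart by at least 3 log2 units, 0.397% (1 gene) set the libraries labelled parental apart the same way by at least 1; the same value argues against a shift shared by both on top of their line differences, and against a batch or RNA quality difference between libraries of the labelled lines as the whole cause, since either would keep those differences. Only 60 genes of 300 nt or more differ between the libraries labelled parental. The share of 0.397% thus follows from their closeness and is not evidence separate from it. A swap with a resistant library is argued against by all 4 resistant libraries being closest to the other resistant library of their line. That both libraries were made from one culture stays open, since the SD of 0.241 between them restates that they lie close; that culture could be a B cell line other than DAUDI and DOHH2, a hypothesis that short tandem repeat typing of the cultures would test. A batch or RNA quality difference as a part of the cause stays open: 90 genes (72 on in the libraries labelled parental, 18 on in the resistant ones) were under 0.1 FPKM in one set and at 10 FPKM or more in every library of the other, between the bounds of 20 and 100 set beforehand.

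Differences from the libraries labelled parental are shared by the lines. A shared control could give this. For unrelated cultures equally far apart r would lie near 0.5, and the mean of both drugs was 0.61, between the bounds of the test. The cultures are not equally far apart, however. For features of 300 nt or more, the SD from the library labelled parental to the idelalisib-resistant one was 1.34 in DAUDI and 1.36 in DOHH2. Between these idelalisib-resistant libraries it was 1.01. The value of 0.5 therefore does not apply, and the test cannot decide what part is shared by resistance. A biological explanation, that both lines took on the same changes with resistance, was not tested, as no parental library that groups with its line is at hand.

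In DAUDI the ibrutinib-resistant library differs from the idelalisib-resistant one more than in DOHH2. Against greater depth as the whole cause, 32.5% of the 342 differing genes (111 genes) had a mean of 10 FPKM or more, where genes near the floor would be needed; among all genes of 300 nt or more it was 42.2%, so that a part of the difference from depth stays open. A library or sequencing batch stays open: with 1 library, whose depth is 1.42 times that of the DAUDI library labelled parental, batch and state cannot be told apart. The biological explanation, a difference between the drugs in DAUDI, stays open as untested.

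The median of the interferon response list was on opposite sides of the library labelled parental in the lines, which picked it out, with DOHH2 minus DAUDI at -3.005 for idelalisib and -3.69 for ibrutinib resistance; the difference was not tested. For MHC class I the values were -2.20 and -2.12, not tested. For MHC class II they were -2.26 and -2.14, not tested. Isoforms without a gene name, not used here, took a larger percentage of all FPKM than in either library labelled parental (0.636 in DAUDI, 1.32 in DOHH2) in the ibrutinib-resistant DAUDI library (1.55) and in the idelalisib-resistant (2.75) and ibrutinib-resistant DOHH2 libraries (2.40). For DOHH2 minus DAUDI over all libraries, the 10 splits of 3 and 3 libraries are too few for a share under 0.05: the real split gave 0 genes and the highest other 25.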

How the results depend on the processing

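Of the alternatives below, the other line's library labelled parental, features of 300 nt or more and the comparison of lines in resistant libraries only were chosen after seeing the data. Of 335 alternatives for counts and correlations, 266 stayed within their bounds and 69 moved; of 2409 for single genes and list medians, 2112 stayed, 116 lost and 14 gained a call, 165 moved and 2 were reversed. With a pseudocount of 5, which shrinks every difference by construction, genes higher and lower were 839 and 986 (DAUDI idelalisib), 1243 and 942 (DAUDI ibrutinib), 927 and 1011 (DOHH2 idelalisib) and 853 and 988 (DOHH2 ibrutinib); both lines shared 417 and 648 with idelalisib and 430 and 601 with ibrutinib resistance, and both drugs 744 and 855 in DAUDI and 754 and 926 in DOHH2. With a pseudocount of 0.1 both lines shared 1513 genes higher with idelalisib resistance. With the other line's library labelled parental the counts stayed at 1936 and 1977, 2513 and 1799, 1936 and 1894, and 1810 and 1885 in the same order. At 5 FPKM or more the median of drug transport genes was reversed in DAUDI (0.84 and 0.77); the cause was not tested. Genes with a changed isoform share, in the same order, were 3, 6, 9 and 6 at 30 FPKM and 5, 10, 8 and 6 at 70 points, as stricter limits must give fewer.

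In limma with no filter 389 genes rose and 1014 fell with idelalisib and 419 and 984 with ibrutinib resistance (335, 672, 359 and 647 of them also in the filtered fit); the cause was not tested. With only the 4 libraries of the states compared, which leaves 1 residual degree of freedom, 34 rose and 116 fell with idelalisib and 0 and 0 with ibrutinib resistance, and 0 fell between the drugs. Without each library in turn, where a lone sample is assumed to vary like the others, genes rose from 0 to 1287 and fell from 0 to 1622 (idelalisib), rose from 0 to 1415 and fell from 0 to 1517 (ibrutinib), fell from 0 to 0 between the drugs, and were higher from 0 to 799 and lower from 0 to 942 in DOHH2. All counts of 0 for the resistance contrasts came from leaving out a resistant library. Without the block for the cell line 1122 rose and 1254 fell with idelalisib and 1251 and 1202 with ibrutinib resistance, and between the drugs 1 rose and 2 fell. Between the drugs 1 rose at 5 FPKM or more, 1 rose with the most abundant isoform, 0 fell with no filter and 0 fell among features of 300 nt or more, where SNORD83B is left out. In resistant libraries only, 868 genes were higher and 1046 lower in DOHH2, where the nearly alike libraries labelled parental no longer enter the fit. With an estimated correlation camera called 0, 0 and 0 lists for idelalisib, ibrutinib and the drugs compared.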
